A study of Mus musculus with 10 samples.

How the data were processed

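Gene expression in the renal cortex of 10 mice was measured with Affymetrix mouse arrays, 1 array per mouse. Per the labels' protocols, biotin-labelled cRNA was made from 100 ng of total RNA. The authors deposited log2 expression values, 1 per probe set, made with RMA in Affymetrix Expression Console 1.1 per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and combines the probes of a set, so an overall difference in RNA amount between mice is no longer visible. The table held 45101 probe sets with values between 2.096 and 15.062 and no missing value, and the array medians lay between 5.521 and 5.564. No pair among the 45 pairs of arrays held identical values. Arrays have no sequencing depth, and their number, 5 per group, limits the precision.

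After 64 control probe sets were left out, 45037 remained. In the platform annotation used here, 34945 of them had 1 gene symbol, 932 had several and 9160 had none, and genes were named only from probe sets with 1 symbol. The gene identifiers of 34741 of these probe sets were found in a RefSeq gene table. No genome build is named with the values, so no coordinates are given. The 34945 probe sets stood for 18193 genes, 9010 of them with several probe sets. Each gene was represented by its probe set of highest mean over the 10 arrays, and a gene was tested where that mean reached the median of all non-control probe sets, 5.53 on the log2 scale. This left 11486 genes. Some genes of the lists and readouts were not analysed here, and Agtr1b, Tgfb1 and Nphs1 lay below the level filter.

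The deposited values were compared without further scaling, as aliskiren minus losartan, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, treatment as the only term) and Benjamini-Hochberg adjustment at 0.05. Genes whose 95% confidence interval lay within 1.5-fold in both directions were counted as having a bounded difference. The share of the total sum of squares that lay between the treatments was tested by exact permutation over the 126 splits of the 10 arrays into 5 and 5. Gene lists for renal cell types, the renin system, steroid response, kidney damage and metabolism, with markers of tissues that a cortex sample could carry along, were tested with limma's camera at a preset inter-gene correlation of 0.01. The 31 lists with at least 3 tested genes were adjusted together. Camera with an estimated correlation, fry and an exact permutation test of each list's mean were run beside it. The mouse number served only as a name.

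The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 5 genes of smallest p in each direction where no gene passes, up to 3 members of smallest p per list, and a fixed set of readouts of the renin system and of kidney damage. It took in 107 genes. The text names 62 of these: for the 24 lists that neither passed the test nor held a member past the threshold within the list, only the member of smallest p is named, a reduction made after the data were seen. Genes outside the rule are named as chosen after their values were seen. Alternatives covered the level filter, the choice of probe set, the scaling between arrays, the variance model, array weights, the mouse number as a block, the threshold, the set test and leaving out each array in turn. A fit with the perirenal fat list as a covariate, a fit without losartan mouse 3 and aliskiren mouse 1, and camera with an estimated correlation without these mice were added after the data were seen.

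The fits were tested on simulated data for aliskiren against losartan, with the means and residual SDs of the 11486 genes, independent normal errors and 200 changed genes. Of the changed genes, 51 of 67 were recovered at 1.5-fold, 59 of 67 at 2-fold and 64 of 66 at 3-fold, and 7 of 11286 unchanged genes were called. Recovery after Benjamini-Hochberg adjustment depends on how many genes change. Fewer than 200 changed genes were not simulated, so these rates do not carry over to such data. Simulated genes vary independently, unlike genes in tissue, and the effect of that difference on the gene and list tests was not measured. Figures were drawn with matplotlib 3.10.9.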

Results

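The samples came from the renal cortex of 10 FVB/N mice aged 20 weeks that had lost renal mass by partial ablation and later by removal of a kidney. Drug treatment began 6 weeks after the ablation and 4 weeks after the uninephrectomy, and lasted 6 weeks. In 1 group of 5 mice the drug was losartan at 500 mg/l, which blocks the type 1 angiotensin II receptor. In the other group of 5 mice it was aliskiren at 50 mg/kg per day, which inhibits renin, the enzyme that releases angiotensin I from angiotensinogen. The design holds 1 comparison, aliskiren against losartan, and asks how the remaining kidney differs in gene expression between the drugs. Untreated mice were not analysed here, so no value speaks to the effect of either drug alone. All values are RMA log2 expression values as deposited by the authors, and errors are SD over 5 mice per group or the SE of a difference. For a single gene the SE is limma's, which moderates the variance across genes. For a list mean it comes from the variances of both groups, so the SEs of genes and lists are not alike.

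Renal expression of the treated groups overlapped for nearly all genes. Of 11486 genes tested with limma, 0 were higher and 0 lower with aliskiren at an adjusted p under 0.05, and the lowest adjusted p was 0.945. At an unadjusted p under 0.05 there were 542 genes, or 4.72% of those tested, and an ordinary t statistic without moderation across genes gave 573 at that level and 0 after adjustment. For 10075 genes, 87.7%, the 95% confidence interval of the difference excluded a change of 1.5-fold or more in either direction. The median absolute difference was 0.07 on the log2 scale. Treatment accounted for 8.25% of the total variance, below the mean of 11.1% over all 126 splits of the arrays (exact permutation p = 0.714).

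The genes of smallest p among those lower with aliskiren did not pass the test after adjustment, and their values are given as such. Scg5, which encodes the neuroendocrine chaperone 7B2, had a log2 value of 9.24 ± 0.28 (SD, n = 5) with losartan and 8.46 ± 0.20 with aliskiren, and losartan mouse 3 stood apart at 9.72. Stc1, encoding the secreted glycoprotein stanniocalcin, had a difference of -0.86 (SE 0.18). Scnn1a, the alpha subunit of the epithelial sodium channel ENaC, had 8.22 ± 0.16 with losartan and 7.82 ± 0.07 with aliskiren, a difference of -0.40 (SE 0.08). Tmem213 differed by -0.36 (SE 0.07) and Phactr1 by -0.41 (SE 0.08). In the other direction Gcnt2, a glycosyltransferase gene, had a difference of 0.46 (SE 0.10), Klhl2 of 0.26 (SE 0.06), E130311K13Rik of 0.33 (SE 0.08), the T cell receptor segment Trav9d-3 of 0.59 (SE 0.15) and Lpar6 of 0.25 (SE 0.06). Except for E130311K13Rik, every aliskiren mouse lay on the same side of every losartan mouse for these genes. Such separation was found for 105 genes, 0.914% of those tested, where chance gives 0.794%.

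**Figure D1:**
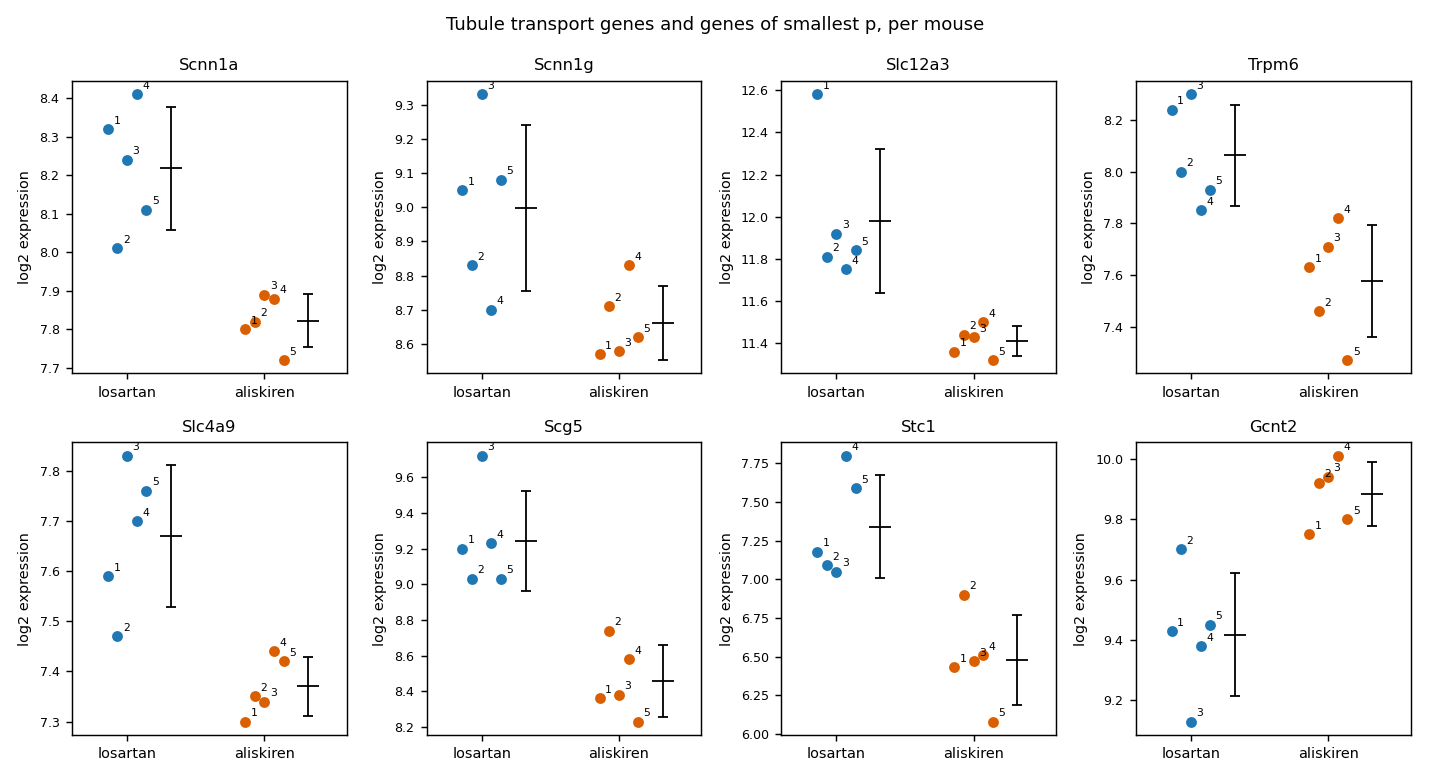
Log2 expression (vertical axis) in each mouse of the losartan and aliskiren groups for 8 genes, with the mouse number beside each point and the mean ± SD of 5 mice as a bar. The groups do not overlap for Scnn1a, Slc12a3, Trpm6, Slc4a9, Scg5, Stc1 and Gcnt2, and they overlap for Scnn1g; none of the 8 passed limma's adjusted threshold.

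Lists of corticosteroid-responsive genes and of collecting duct cells, which fine-tune sodium, potassium and acid excretion, had mostly lower values with aliskiren. The corticosteroid list also holds general glucocorticoid targets such as Fkbp5, Tsc22d3 and Per1. Of 15 tested genes that respond to corticosteroids and aldosterone, 12 had a lower value and the mean difference was -0.25 (SE 0.10). Scnn1a, Scnn1g at -0.34 (SE 0.11) and Scnn1b at -0.35 (SE 0.13), the ENaC subunits, had the smallest p in this list, and Scnn1b was at -0.22 without losartan mouse 3. Scnn1g and Scnn1b also led the collecting duct principal cell list, with the potassium channel gene Kcnj10 at -0.32 (SE 0.11). Scnn1b, Scnn1g, Hsd11b2 and Fxyd4 belong to both lists, so the lists are not independent. In the principal cell list 11 of 13 genes were lower, by -0.22 (SE 0.14) on average, with aliskiren mouse 4 apart from its group at 9.18 and losartan mouse 3 highest of all at 9.25. Without losartan mouse 3 and aliskiren mouse 1 the difference was -0.12, and it passed at the preset correlation (adjusted p = 0.00454) but not with an estimated correlation (adjusted p = 0.923). Of 14 intercalated cell genes, those of the acid- and base-secreting cells of the collecting duct, 12 were lower, by -0.14 (SE 0.07) on average, among them the anion exchanger gene Slc4a9 at -0.30 (SE 0.07), the proton pump subunit gene Atp6v1b1 at -0.20 (SE 0.06) and the transcription factor gene Foxi1 at -0.40 (SE 0.13).

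These 3 lists passed camera with the preset correlation, at adjusted p = 0.000398 for corticosteroid response, 0.000337 for principal cells and 0.000398 for intercalated cells. None kept its call with an estimated correlation, where the adjusted p = 0.509 with an estimated correlation for the first and 0.567 for the other two. Over all genes tested 0 members passed limma's threshold, and adjusted over the list alone 1 corticosteroid gene (Scnn1a, adjusted p = 0.00708), 0 principal cell genes and 1 intercalated cell gene (Slc4a9, adjusted p = 0.0264) did. Adjustment over the list alone does not correct for the 31 lists tested, so some such members can arise by chance. The loop of Henle and distal tubule list went both ways, with 9 of 15 genes lower, a mean difference of -0.06 (SE 0.11) and a camera adjusted p of 0.565. Adjusted over the list alone, 2 of its genes passed: Slc12a3, the thiazide-sensitive sodium chloride cotransporter, had 11.98 ± 0.34 (SD) with losartan and 11.41 ± 0.07 with aliskiren, with losartan mouse 1 apart at 12.58, and the magnesium channel gene Trpm6 had a difference of -0.49 (SE 0.12), both at a limma adjusted p of 0.0175 within the list. Cldn10, a claudin of the thick ascending limb, had a value of 0.35 (SE 0.12) in the other direction.

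Cell cycle genes had lower values with aliskiren in 16 of 17 cases, with a mean difference of -0.35 (SE 0.23). Cdk1, the mitotic kinase, differed by -0.60 (SE 0.25), Ube2c by -0.53 (SE 0.21) and the replication clamp gene Pcna by -0.27 (SE 0.14), or -0.16 without losartan mouse 3. Endothelial genes were lower in 16 of 20 cases by -0.14 (SE 0.13) on average, with the vascular growth factor receptor genes Flt1 at -0.31 (SE 0.10) and Kdr at -0.29 (SE 0.15) and the angiopoietin receptor gene Tek at -0.30 (SE 0.16). The Y-linked genes Kdm5d at 0.23 (SE 0.08), Uty at 0.18 (SE 0.07) and Eif2s3y at 0.00 (SE 0.08) formed the sex chromosome list, with a mean difference of 0.14 (SE 0.04). Camera's preset correlation gave adjusted p = 0.000277, 0.0086 and 0.029 for these 3 lists. With an estimated correlation the adjusted p = 0.959 for cell cycle and endothelial genes and 0.509 for the sex chromosome list. Adjusted over the list alone, 0 cell cycle, 0 endothelial and 2 sex chromosome genes passed limma's threshold, and over all genes 0 did. The endothelial call ended without losartan mouse 1 or 3 or aliskiren mouse 3 or 5, with adjusted p up to 0.161, and its mean difference ran from -0.06 without losartan mouse 3 to -0.23 without losartan mouse 4. The sex chromosome call ended without losartan mouse 2 or 3 or aliskiren mouse 1, 3 or 5, with adjusted p up to 0.0771. The cell cycle difference was -0.22 without losartan mouse 2. With the level filter at the 75th percentile the cell cycle and endothelial calls ended (adjusted p = 0.191 and 0.0969), and the sex chromosome call ended with array medians set equal (0.0558), with array weights (0.0632) and with no level filter (0.0599).

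In all, 6 of the 31 lists passed at the preset correlation, 5 lower and 1 higher with aliskiren. With array medians set equal 6 passed, 6 lower and 0 higher. The count was 0 with an estimated correlation and 0 with fry's directional test. Exact permutation of the list means gave 0 as well after adjustment, which was nearly fixed by the design. The sex chromosome list had the smallest p that 5 against 5 mice can give, 0.00794, and its adjusted p was 0.246. The design did not fix the unadjusted exact permutation p of the other lists called at the preset correlation. These were 0.0397 for corticosteroid, 0.0794 for intercalated cell, 0.143 for principal cell, 0.19 for cell cycle and 0.349 for endothelial genes. Fry's mixed test, which asks for change in either direction, passed for the corticosteroid list (adjusted p = 0.0359). Of 100 splits of the same arrays into 5 and 5, the real one included, 82 gave at least 6 lists. The splits other than the real one gave a median of 9 lists. In the lists that did not pass, apart from the loop and distal tubule genes, 0 members passed limma's threshold adjusted over the list alone. Without losartan mouse 3 the mean difference of 14 of the 31 lists turned in sign and that of 11 more changed by a factor above 1.5. Of the differences of single genes given in this text 7 turned and 17 changed by such a factor.

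Readouts of kidney damage differed far more between mice than between drugs. Havcr1, which encodes the tubular injury marker KIM-1, had 7.66 ± 2.12 (SD) with losartan and 7.67 ± 1.36 with aliskiren, and Lcn2, which encodes neutrophil gelatinase-associated lipocalin, had 7.20 ± 2.09 and 7.47 ± 0.85. The 95% interval of the Havcr1 difference ran from -2.18 to 2.21. The tubular injury list, 20 genes, had a mean difference of -0.11 (SE 0.54, camera adjusted p = 0.631), and its member of smallest p was the keratin gene Krt19 at -1.10 (SE 0.48), which stood at 9.07 in losartan mouse 3. Without that mouse the list's mean difference turned to 0.32 and passed camera's preset threshold (adjusted p = 0.0305), where the adjusted p = 0.837 with an estimated correlation. Without aliskiren mouse 1, the highest of its group at 9.65, as well, the difference was 0.11 and did not pass (adjusted p = 0.637). Without aliskiren mouse 1 alone it was -0.32 and did not pass either (adjusted p = 0.135). The differences of Havcr1, Lcn2 and Krt19 without losartan mouse 3 were 0.79, 1.02 and -0.63. Of 29 fibrosis and extracellular matrix genes 26 had a lower value with aliskiren, at a mean difference of -0.22 (SE 0.42) that did not pass camera (adjusted p = 0.0789). Col1a1 differed by -0.10 (SE 0.51), Col3a1 by 0.02 (SE 0.65), the fibronectin gene Fn1 by -0.27 (SE 0.45), the growth factor gene Ccn2 by -0.47 (SE 0.34) and Col6a1 by -0.42 (SE 0.29). These were 0.39, 0.55, 0.14, -0.25 and -0.22 without losartan mouse 3. At the preset correlation the fibrosis list passed with array medians set equal (adjusted p = 0.00436), with quantile normalization (0.0309) and when losartan mouse 1, 4 or 5 or aliskiren mouse 1 was left out, at -0.26, -0.43, -0.33 and -0.39. Without losartan mouse 3 its mean difference turned to 0.12 and did not pass (adjusted p = 0.112), without aliskiren mouse 4 it was -0.09, and with all mice the adjusted p = 0.959 with an estimated correlation.

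Genes of the renin-angiotensin system showed no difference past the threshold. The 11 tested members had a mean difference of -0.01 (SE 0.06, camera adjusted p = 0.712). Agt, which encodes angiotensinogen, differed by -0.16 (SE 0.29), the converting enzyme gene Ace by 0.25 (SE 0.21) and the receptor gene Agtr1a by -0.08 (SE 0.16). The Ace difference was 0.04 and that of Agt -0.01 without losartan mouse 3, which had Ace at 7.52. Hsd11b2, which encodes the enzyme that keeps glucocorticoids off the mineralocorticoid receptor, had the smallest p in this list at -0.30 (SE 0.12). Genes of renin cells and the macula densa had a mean difference of -0.03 (SE 0.12, adjusted p = 0.952), with the prostaglandin E synthase gene Ptges at -0.45 (SE 0.17), or -0.27 without losartan mouse 3, where it stood at 7.14. The list mean turned to 0.05 without that mouse.

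Macrophage, chemokine, interferon and matrix-degrading enzyme lists depended on single mice. Among these were losartan mouse 3, in which the perirenal fat list reached 12.20 as well, and aliskiren mouse 1. Leaving out losartan mouse 4 or losartan mouse 5 also turned all 4 mean differences to negative values. With all mice, macrophage and myeloid genes differed by 0.08 (SE 0.54, camera adjusted p = 0.631), chemokine and NF-kB genes by 0.01 (SE 0.37, adjusted p = 0.952), MHC class II and interferon genes by 0.02 (SE 0.31, adjusted p = 0.631) and matrix-degrading enzymes and inhibitors by 0.05 (SE 0.21, adjusted p = 0.363). Each passed camera's preset threshold as higher with aliskiren when losartan mouse 3 was left out, at mean differences of 0.48, 0.31, 0.24 and 0.19, and for each the adjusted p = 0.73 with an estimated correlation. Without aliskiren mouse 1 as well, the differences were 0.26, 0.18, 0.16 and 0.06; the first 3 passed at the preset correlation and matrix-degrading enzymes did not (adjusted p = 0.22), and with an estimated correlation the adjusted p = 0.923 for all 4. Without aliskiren mouse 1 alone the differences turned to -0.14, -0.11, -0.06 and -0.07, and none passed (adjusted p = 0.881). The members of smallest p were Ccr2 at 0.11 (SE 0.13), Nfkb2 at -0.14 (SE 0.08), Mx2 at 0.17 (SE 0.08) and Timp3 at 0.25 (SE 0.10), where Ccr2 was at -0.01 and Nfkb2 at -0.06 without losartan mouse 3. The chemokine gene Ccl2 differed by -0.19 (SE 0.56), and by 0.30 without that mouse. Lymphocyte genes, of which only 5 of 22 were tested, differed by 0.01 (SE 0.24, adjusted p = 0.63), with Cd4 at 0.19 (SE 0.11). The list's difference was -0.02 without losartan mouse 3 and -0.14 without aliskiren mouse 1. Complement and coagulation genes differed by -0.07 (SE 0.29, adjusted p = 0.952). Without losartan mouse 3 they differed by 0.16, which did not pass (adjusted p = 0.0555), and without aliskiren mouse 1 by -0.19. Cd55 was at 0.28 (SE 0.21) with all mice and at 0.09 without losartan mouse 3.

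**Figure D2:**
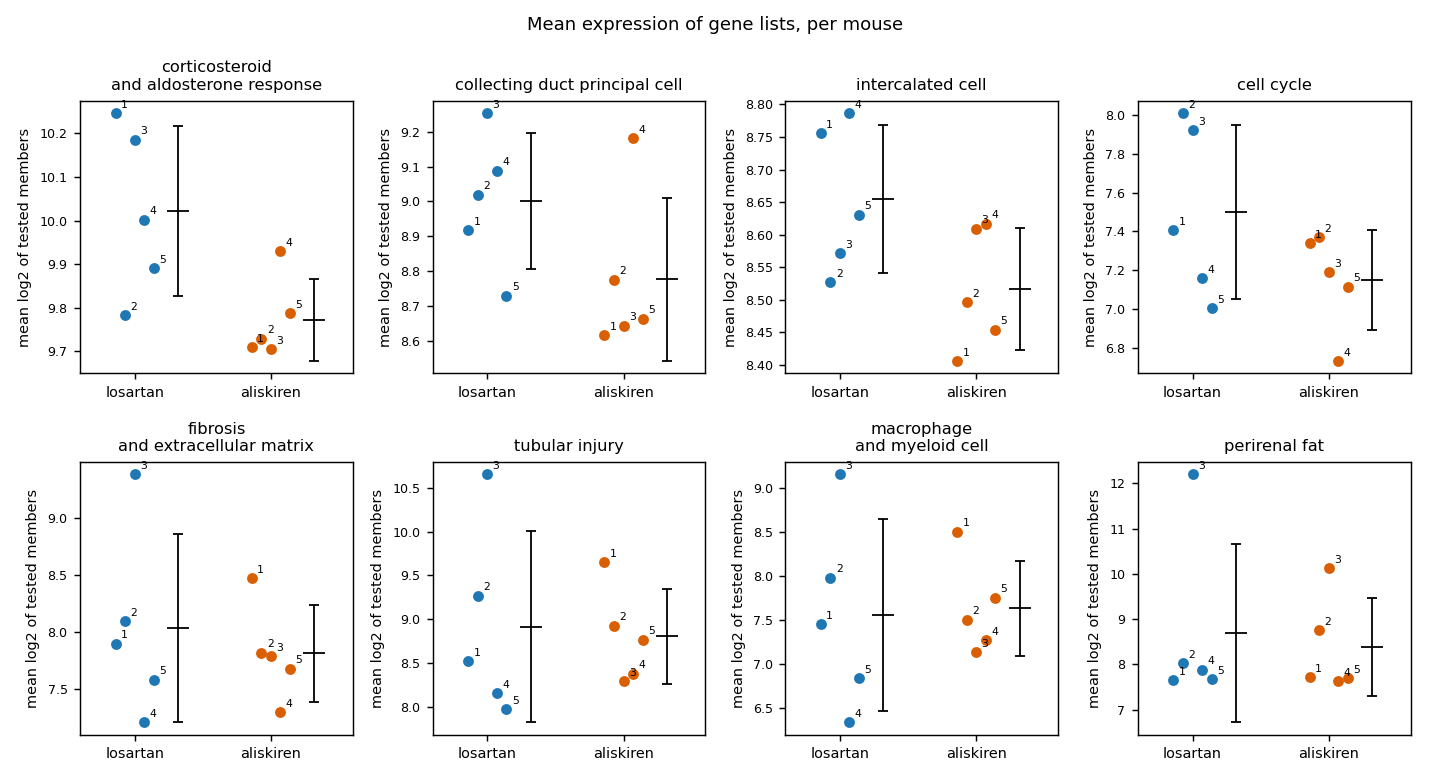
Mean log2 value of the tested members of 8 gene lists (vertical axis) in each mouse of the losartan and aliskiren groups, with the mouse number beside each point and the mean ± SD of 5 mice as a bar. Losartan mouse 3 has the highest value of the 10 for the fibrosis, tubular injury, macrophage and perirenal fat lists, at 9.39, 10.65, 9.16 and 12.20.

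No other list passed camera. Proximal tubule genes, the bulk of the cortex, differed by 0.03 (SE 0.09, adjusted p = 0.631). Cyp4b1 was at 0.35 (SE 0.17), and at 0.18 without losartan mouse 3. Podocyte genes differed by -0.02 (SE 0.16, adjusted p = 0.712), with Actn4 at -0.17 (SE 0.08), and passed at the preset correlation without losartan mouse 4, at -0.15. Oxidative phosphorylation genes differed by 0.01 (SE 0.03, adjusted p = 0.631), with the cytochrome c gene Cycs at 0.16 (SE 0.09). Fatty acid oxidation genes differed by -0.06 (SE 0.10, adjusted p = 0.363), with Hadha at -0.23 (SE 0.08), and passed at the preset correlation without aliskiren mouse 5, at -0.09. The loop and distal tubule list passed in the same way without aliskiren mouse 4, at -0.14. With all mice the adjusted p = 0.959 with an estimated correlation for each of the podocyte, fatty acid oxidation and loop lists. Cholesterol synthesis genes differed by -0.12 (SE 0.10, adjusted p = 0.363), with Idi1 at 0.22 (SE 0.09). Idi1 was lowest in losartan mouse 1, at 10.16, and its difference was smaller without that mouse. Genes of hypoxia and glycolysis differed by -0.05 (SE 0.11, adjusted p = 0.712), with Pgk1 at 0.12 (SE 0.07). Genes of oxidative stress and NRF2 differed by -0.05 (SE 0.11, adjusted p = 0.952), with the catalase gene Cat at 0.26 (SE 0.13). Endoplasmic reticulum stress genes differed by 0.00 (SE 0.05, adjusted p = 0.631), with Chac1 at 0.17 (SE 0.08), immediate early and heat shock genes by -0.13 (SE 0.15, adjusted p = 0.363), with Ier3 at -0.80 (SE 0.26), and circadian clock genes by -0.12 (SE 0.14, adjusted p = 0.464), with Per1 at -0.49 (SE 0.27) and aliskiren mouse 1 apart from its group at 8.16. Without aliskiren mouse 1 the clock difference was 0.00, and without losartan mouse 3 as well it was -0.01. Without losartan mouse 3 alone the differences were -0.14 for the clock list, -0.01 for immediate early genes and -0.04 for cholesterol synthesis. Those of hypoxia and oxidative stress turned to 0.04 and 0.05. Proximal tubule, podocyte, oxidative phosphorylation, fatty acid oxidation and endoplasmic reticulum stress turned as well, to -0.02, 0.04, -0.02, 0.01 and 0.01. The loop list was at -0.12 without that mouse.

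Lists for tissue that a cortex sample could carry along did not differ past the threshold either. Medulla and papilla genes differed by 0.03 (SE 0.17, adjusted p = 0.712), with the water channel gene Aqp2 at -0.47 (SE 0.24), and adrenal cortex genes by 0.02 (SE 0.09, adjusted p = 0.646), with Nr5a1 at 0.17 (SE 0.11). Red blood cell genes differed by -0.01 (SE 0.16, adjusted p = 0.897), with Slc25a37 at 0.06 (SE 0.08). Only 4 of 9 adrenal cortex genes and 3 of 8 red blood cell genes were tested, so both lists could miss such tissue. Perirenal fat genes differed by -0.30 (SE 1.00, adjusted p = 0.646), with Pparg at -0.44 (SE 0.53), and passed with the direction turned, at 0.58, without losartan mouse 3 (adjusted p = 0.0417, and 0.73 with an estimated correlation). The list reached 12.20 in losartan mouse 3 and 10.13 in aliskiren mouse 3 against 7.66 in losartan mouse 1. For 7 lists that did not pass, the median, the mean and camera's direction differed in sign: matrix-degrading enzymes, lymphocyte, proximal tubule, endoplasmic reticulum stress, red blood cell, complement, and renin cell and macula densa.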

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

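The tests of the injury genes, of the collecting duct, intercalated cell and corticosteroid lists and of the counts at an unadjusted p and of bounded differences were chosen after the values were seen; the tests of other fat genes and other clock genes, and the split counts for genes and lists past the threshold, were written before their outcome was known. The bounds that decide the tests of fat against injury genes, cell share, clock phase and bounded differences were reset once after their values were seen. A value is listed here where 1 mouse stood apart from the other 4 of its group, measured as the gap to the nearest mouse over the range of the group (above 0.71). Of 188 group values tested 17 met this, and chance gives about 5% of them.

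Losartan mouse 3 held 9 of the 17. Its array had the lowest mean correlation with the other arrays, 0.9806 against 0.9906 to 0.9933 in the other losartan mice (gap over range 0.787). It was highest for the perirenal fat list (0.919), Pparg (0.893), Nfkb2 (0.859), Krt19 (0.732), Ccl2 (0.723) and Scg5 (0.714), and lowest for the oxidative phosphorylation list (0.855) and the sex chromosome list (0.856). Aliskiren mouse 1 stood highest for the podocyte (0.728) and lymphocyte lists (0.744) and lowest for the circadian clock list (0.831). Aliskiren mouse 4 stood highest for the loop of Henle and distal tubule list (0.943) and the collecting duct principal cell list (0.719). Aliskiren mouse 2 was lowest for Timp3 (0.715), and losartan mouse 1 was highest for Slc12a3 (0.789) and lowest for Mx2 (0.735).

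The fat genes of losartan mouse 3 may come from fat tissue in the sample. Of 8 fat genes not looked at before and with a probe set of their own, 7 were highest in that mouse. The exception, Elovl3, was highest in aliskiren mouse 3. Adipoq, Cidec, Lep and Ucp1 were on the perirenal fat list as written but below the level filter, so the 8 genes are no independent set. Losartan mouse 3 had Adipoq at 12.96 and Ucp1 at 9.31 against medians of 3.70 and 3.72. Fat as the source of its tubular injury and macrophage genes stays open: of 39 members highest in losartan mouse 3, 94.9% stayed below 50% of the signal expected from fat in aliskiren mouse 3, whose fat signal was 13.4% of that in losartan mouse 3. In aliskiren mouse 2 35.9% did, but at a fat signal of 2.15% that mouse says little. The evidence against fat thus rests on 1 array and on 1 share for all fat genes. In aliskiren mouse 3 that share ran from 8.54% to 29.9% over the 6 genes of the list. Ucp1 was 8.87 there against 9.31 in losartan mouse 3, and Lep 3.38 against 5.87, so the share may not carry over to other genes. Lower RNA quality of losartan mouse 3 is argued against, since its 3' minus 5' log2 signal of actin and Gapdh, 1.11, lay within the 0.94 to 1.41 of the other arrays. No biological explanation was tested for a single mouse, and more severe kidney damage in it remains open.

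Several clock genes of aliskiren mouse 1, chosen after their values were seen, lay apart from all 9 other mice. Arntl was at 9.03 against a median of 6.24, and Dbp at 7.99 against 11.31. Per2, Per3, Nr1d2 and Ciart were lowest in that mouse, at 6.29, 7.03, 10.57 and 5.56 against medians of 8.44, 8.4, 11.63 and 7.0. Nfil3 was highest in it, at 8.18 against 6.79. Nr1d1 did not stand apart: it was at 6.04 in that mouse, within the 5.64 to 7.28 of the others. Tissue taken at another time of day may account for this, but the test was indecisive: of 2 further genes of the Arntl phase 1, Npas2, was highest in that mouse, by 0.005 and at a level below the filter, and Cry1 was not. Sampling times were not analysed here, and no biological explanation was tested.

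The lower collecting duct, intercalated cell and corticosteroid lists were weighed against chance, cell share and clock phase. Among 100 of the 126 splits of the arrays 82 gave at least the 6 lists of the real one. The other splits gave a median of 9 lists and at most 16. The count of lists thus does not set the drug split apart, and chance cannot be excluded. A clock shift of aliskiren mouse 1 alone is argued against, since without that mouse and without clock genes at least 80.1% of each list's mean difference was left; 2 of the 3 lists hold no clock genes, so for them only the mouse was left out. A phase difference among the other mice was not tested and stays open: Dbp was 11.49 to 11.62 in aliskiren mice 2 to 5 against 10.41 to 11.51 in the losartan mice, and Cry1 4.08 to 5.26 against 3.89 to 6.48, where losartan mouse 2 gave the 11.51 and the 3.89. A lower share of collecting duct cells in the aliskiren samples cannot be told apart from lower expression per cell: the 23 markers of these cells outside the corticosteroid list differed by -0.16 (exact permutation p = 0.0794, two-sided). The 3 ENaC subunits differed by a further -0.20 (exact permutation p = 0.0476), which the first bound would have read against cell share, but they were among the genes of smallest p and so exclude nothing; sections to count cells were not analysed here. A difference between the drugs in mineralocorticoid action remains open and untested.

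All 100 splits gave at least the 0 genes past the threshold of the real split, with 1 as the highest, but any split meets a count of 0, so this says nothing about chance. For single genes 29 splits gave at least its 542 genes at an unadjusted p under 0.05, with 1584 as the highest. For the count of bounded differences 50 of 100 splits gave at least 10075, with 10283 as the highest. Chance cannot be excluded for either of these counts. A split that gives 1584 genes points to a structure among the mice that does not follow the drugs.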

How the results depend on the processing

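The fit with perirenal fat as a covariate, the fit without losartan mouse 3 and aliskiren mouse 1, and estimated correlations without these mice were chosen after seeing the data. The count of genes past the threshold was 0 under every alternative run, and 0 without any one array. The share of variance between treatments did not pass its test under any alternative, and ranged from 7.29% to 13.1% over fits without one array. Bounded differences numbered 16289 with no level filter and 6370 with the filter at the 75th percentile, as these test more and fewer genes, and 9745 to 10586 without one array. Lists past the threshold numbered 3 at the 75th percentile, 0 with an estimated correlation, 0 with fry's directional test, 0 with exact permutation of list means, where the smallest p that 5 against 5 mice can give, 0.00794 for the sex chromosome list, was adjusted to 0.246, and 4 to 10 without one array, with 10 without losartan mouse 3. Camera's estimated correlation was 0.573 for cell cycle and 0.446 for endothelial genes, against the preset 0.01. For principal cell, intercalated cell and corticosteroid genes it was 0.313, 0.22 and 0.132. The preset thus assumed far less correlation between members than was estimated for these lists. The sex chromosome list, at -0.0224, was an exception. The cause was otherwise not tested. Fewer genes enter at the 75th percentile; fry and permutation differ from camera in the null hypothesis as well as in allowing for correlation between genes. The added fits gave 6 and 9 lists, and with an estimated correlation 0 lists without losartan mouse 3 and 0 without both mice.

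With the mouse number as a replicate block, 0 genes and 7 lists passed, fibrosis being the list gained (adjusted p = 0.0106), 10064 differences were bounded, and the share of variance within blocks was 16.2% (exact permutation p = 0.812). The number is not shown to pair the mice: deviations of same-numbered mice correlated between -0.229 and 0.42, and 4 of 10 arrays correlated best with their own number.

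Among the named genes' differences under the alternatives, 2030 kept their direction and none passed, and 60 changed sign without passing. Among list means 539 kept direction and side, 33 lost and 17 gained a call, and 87 that had not passed changed sign. Of these 87, 3 passed after the change: tubular injury at 0.32 and perirenal fat at 0.58 without losartan mouse 3, and perirenal fat at 0.74 without that mouse and aliskiren mouse 1. None of these 3 passed camera with an estimated correlation (adjusted p = 0.837, 0.73 and 0.923). The calls for the corticosteroid, principal cell, intercalated cell and cell cycle lists held without any one array at camera's preset correlation. For the cell cycle list, losartan mice 2 and 3 were both high, and leaving out 1 array at a time cannot show their joint weight. With an estimated correlation and all mice none of the 4 lists passed (camera adjusted p = 0.509, 0.567, 0.567 and 0.959). Genes below 5.53 on the log2 scale were not tested in the main setting; with no level filter 760 genes had an unadjusted p under 0.05.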

Other observations

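The values here were chosen after they were seen. The first principal component over the tested genes held 54.2% of the variance, and losartan mouse 3 lay at 52.18 on it against -20.29 to 11.07 for the other 9 mice. Tubular injury and macrophage genes were high in mice of both groups: Havcr1 reached 10.76 and Lcn2 10.19 in losartan mouse 3, and 9.37 and 8.55 in aliskiren mouse 1, against 5.41 and 4.96 in losartan mouse 5. The macrophage and myeloid list stood at 9.16, 8.51 and 6.84 in these 3 mice. Slc7a13, a cystine transporter gene of the proximal tubule, was at 10.47 in losartan mouse 3 and had a median of 13.20 over the 10 mice, while the proximal tubule list was at 11.92 in that mouse and at 12.24 in losartan mouse 5. Ighm, the heavy chain gene of immunoglobulin M, was at 9.75 in losartan mouse 2 and at 7.30 to 7.45 in the other losartan mice. In the aliskiren group it had a mean of 7.65 ± 0.66 (SD, n = 5), with aliskiren mouse 1 at 8.80. The difference between the groups was -0.20 (SE 0.49).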
